A study of Danio rerio with 15 samples.

How the data were processed

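The samples were pools of 8 to 10 whole larvae, 5 per group, taken at 100 hours after fertilization, per the labels. Per the labels the exposure lasted 3 days, the larvae came from 3 experimental replicates with embryos of 20 breeding pairs, and the libraries were made with a stranded mRNA kit and sequenced as pairs of 100 nt reads to a stated 25 M reads. Which library belongs to which experimental replicate is not given in the sources used here, so no batch term could enter. The p-values of single genes then measure the spread between pools of larvae, which share parents and days to a degree that is not given.

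Per the submitters' processing notes the authors used FastQC, cutadapt, STAR, featureCounts and DESeq2, with no versions given, and per the file headers the gene models were a GTF file of version V4.3.2. The genome build is not given in the sources used here, so no coordinates are reported. Gene symbols and Entrez identifiers are those that the deposited tables pair with each gene. Of 36351 genes, 29219 have an Entrez identifier and 24216 a symbol that is more than a transcript, clone or locus number, and 458 share a symbol with another gene. Whether the counting used strand or kept reads that match several places is not given, so near-identical copies (the hsp70, gamma crystallin, trypsin and chitinase families, and duplicated genes such as hsp90aa1.1 and hsp90aa1.2) are uncertain as single genes.

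The deposited tables give per gene a mean signal, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value. The mean signal, called base mean in the file headers, was computed by the authors with DESeq2 as the mean over the libraries of read counts divided by each library's size factor. The log2 fold change and its standard error, both in log2 units, come from the authors' DESeq2 fit and were shrunken toward 0 before they were deposited, as the values showed. The Wald score equals the deposited fold change over its standard error in every gene tested, and the deposited p-value is its two-sided normal p. The deposited adjusted p-value equals a Benjamini-Hochberg adjustment over the genes that the authors' filter on low means kept, which were 22223 genes with a base mean of at least 13.8 in the TCPM table and 21491 genes with at least 18.4 in the TCPMOH table. The tables hold summary values with no column per library, and 0 columns of per-sample values were left unused. Planned fits of edgeR or DESeq2 to counts, the removal of each library in turn, other normalizations, other splits of the libraries, split controls and an estimated correlation between genes were therefore not run.

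The libraries behind each fit were read from the values. A gene with a single read in a single library has a base mean that depends on that library's size factor alone, and such genes took 8 values in each table. That gave 8 libraries per fit and their size factors, 0.859 to 1.22 in the TCPM table and 0.897 to 1.27 in the TCPMOH table. Multiplied by the summed base means these are 18.2 to 25.9 M and 18.1 to 25.7 M reads assigned to genes. By group the size factors were 0.859 to 1.22 for DMSO and 0.894 to 1.11 for TCPM in the first fit, and 0.897 to 1.27 for DMSO and 0.929 to 0.998 for TCPMOH in the second.

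The direction of the fold changes was settled the same way. Lone-read genes of 4 libraries in each table, 548 and 654 genes, were at 0 in the other table in 0 cases, so these libraries entered both fits and are DMSO. Of the lone-read genes of the other 4 libraries 412 of 627 and 292 of 526 were at 0 in the other table. Genes read in the shared libraries alone had positive deposited fold changes, so the tables give DMSO over compound, and all signs were turned. As a second check the DMSO mean implied by each table was compared over 16488 genes. The log2 ratio of the implied means had an SD of 0.0181 with turned signs and 0.104 with deposited signs.

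Fold changes before shrinkage were recovered by undoing a normal prior, whose SD was 0.216 in the TCPM table and 0.248 in the TCPMOH table, as given by the largest standard errors. Over 655 called genes the mean absolute log2 gap between the DMSO means implied by the tables dropped from 0.0225 with deposited fold changes to 0.0036 before shrinkage. Folds given as times higher or lower are before shrinkage, and log2 fold changes against DMSO are the deposited ones unless said otherwise.

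Genes with a deposited adjusted p under 0.05 were called changed. The compounds were compared by the difference of their log2 fold changes, TCPMOH minus TCPM, over its standard error, in which the covariance from the shared DMSO libraries was set to the product of the standard errors divided by 2, as equal group sizes give. A two-sided normal test with Benjamini-Hochberg adjustment was applied to 22732 genes with a base mean of at least 10 in both tables, and 95% intervals were computed per gene. The difference keeps the deposited, shrunken scale, on which the DMSO libraries do not cancel fully because the priors of the tables differ, and it was computed again before shrinkage, where they do. On both scales its standard error still depends on the DMSO libraries, through the standard errors of both tables and the assumed covariance. Correlation and overlap between the compounds were set beside 100 simulated draws of unchanged groups that share 4 controls, and beside the overlap of independent lists.

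Fixed gene lists, 35 of them, covered the exocrine and endocrine pancreas, other tissues of the larva, and pathways of xenobiotic, lipid and stress biology. Of 1154 listed names 1100 were found, 1068 as symbols and 32 as synonyms in a RefSeq gene table of assembly GRCz12tu, which was used for names alone, and 54 were not found. The ribosomal list took every symbol of its kind. Lists with at least 5 measured genes were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the turned Wald scores, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. A correlation of 0.05 was tried beside it, since none could be estimated without values per library. With it 13 of 18 lists with TCPM, 9 of 14 with TCPMOH and 7 of 7 for the difference passed. Each list's count of members past the threshold was also adjusted over the list alone, and its median was ranked among 10000 random lists matched on base mean in 50 bins. For 6 lists added after the data were seen the results stand in the closing section.

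Genes were named by a rule that took 112 genes: per comparison the 6 with the largest change and the 4 with the smallest adjusted p in each direction (called, with a base mean of at least 20 and a symbol), the 3 best members of each list past its test or with 3 called members, the 8 best genes called with both compounds, the 5 best of the difference in each direction, and 9 genes chosen for the pancreas and xenobiotic response whatever their result. Genes outside the rule are named as chosen after their values were seen. The design, the lists, this rule and the alternatives were fixed before the data were examined, except 3 alternatives that use fold changes before shrinkage. The alternatives were other thresholds, other adjustments and filters on low means, an empirical null, centred fold changes, the difference without covariance, and other correlations, statistics and ranks for the list test.

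The fit per gene, the difference between the compounds and the cameraPR list test were first tested on simulated data. The matched random lists, the ranks, the adjustment over a list alone, the overlap, the correlation and Fisher's exact test were not. Counts were drawn for 27492 genes with the libraries' size factors and the spread implied by the standard errors. Each gene was drawn apart from the others, with the same spread in every group, and the fits were given its true spread. Groups of unequal spread were therefore not tried. The 22951 genes with a base mean of at least 10 were tested. Per compound 100 genes of each of 2 sizes were changed, all with a base mean of at least 100, so the recoveries hold for such genes alone. At a true log2 change of 0.5 the fits recovered 86% of the TCPM and 80% of the TCPMOH changes, at 1.0 they recovered 100% and 99%, and each made 8 false calls. True changes of 0.5 had a median of 0.404 and 0.412 as shrunken and of 0.492 and 0.484 after shrinkage was undone. The difference recovered 88.3% of changes of 0.5 and 99.5% of changes of 1.0, with 21 false calls. Of 41 simulated lists of 30 genes out of 27492, the shifted list had an adjusted p of 1.38e-06 and 0 of 40 others passed. The list genes also had a base mean of at least 100 and no correlation between them. This therefore cannot show how often lists whose members move together pass without a shift. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.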

Results

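Transcript levels were measured by stranded mRNA sequencing in whole zebrafish larvae (Danio rerio, AB wild type) that had been kept in water with 0.01% DMSO by volume, 50 nM TCPM or 50 nM TCPMOH from 24 to 100 hours after fertilization. TCPM is tris(4-chlorophenyl)methane and TCPMOH is tris(4-chlorophenyl)methanol. They differ at the central carbon, which carries a hydrogen in TCPM and a hydroxyl group in TCPMOH. Each of the 3 groups had 5 samples of 8 to 10 pooled larvae, 15 samples in all. The authors' deposited tables, 1 per compound, hold DESeq2 results for 36351 genes. Genes with a single read showed that 8 libraries entered each fit, 4 from DMSO and 4 from the compound, and that the same 4 DMSO libraries served both. Which sample of each group was left out is not given in the sources used here. The libraries held an estimated 18.2 to 25.9 M assigned reads in the TCPM fit and 18.1 to 25.7 M in the TCPMOH fit, and at least 1 read was assigned to 32118 and 31944 genes. On the deposited, shrunken scale the median 95% interval of the difference between the compounds was plus or minus 0.19 in log2 over 22732 genes. Shrinkage narrows intervals, so this overstates the precision. For the pancreas gene pdx1 the interval was -0.16 to 0.30 as deposited and -0.31 to 0.59 before shrinkage. The tables give DMSO over compound, so every fold change below was turned to compound over DMSO.

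The comparison of TCPM with DMSO asked which genes of the larva respond to the methane. Larvae given TCPM had more transcript of the light-induced clock gene per2 and DNA repair gene cry5, of the monooxygenase gene cyp1a and other targets of the aryl hydrocarbon receptor, and of most mitochondrially encoded genes. Digestive enzyme genes of the exocrine pancreas and genes of the intestine epithelium were higher as groups. Transcripts of fosab, npas4a, egr4 and egr1, transcription factor genes induced within minutes of cell stimulation, were lower. In the authors' deposited table, DESeq2 called 419 of 22223 genes at an adjusted p under 0.05, of which 282 were higher and 137 lower, beside 1915 genes at an unadjusted p under 0.05. Most changes were small. The median absolute log2 fold change of the called genes was 0.46 before shrinkage, and 26 genes changed by at least 2-fold.

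Before shrinkage per2 (Entrez gene 140633), a repressor in the clock's feedback loop, was 2.95-fold higher, and cry5, a light-activated DNA repair enzyme of the cryptochrome family, was 2.54-fold higher. The authors' deposited table gives log2 fold changes of 1.31 with a standard error of 0.079 for per2 (adjusted p = 4.76e-58) and 1.17 with a standard error of 0.072 for cry5 (adjusted p = 2.38e-55). Also higher in the authors' deposited table were rdh5, a retinol dehydrogenase of the visual cycle, at 1.01 (adjusted p = 1.1e-20), xpc, which recognises DNA damage, at 0.95 (adjusted p = 3.13e-40), lonrf1 at 0.95 (adjusted p = 4.76e-44) and si:ch211-161h7.5 at 1.13 (adjusted p = 1.82e-30). Of 39 measured genes of the circadian clock list, 9 rose and 3 fell over all genes tested, 11 and 5 adjusted over the list alone, and limma's cameraPR placed the list higher with a median log2 fold change of 0.04 and an adjusted p of 2.04e-12. By ranks the same list gave an adjusted p of 0.229. Among the decreases before shrinkage were 4.22-fold for fosab (Entrez gene 394198), 3.70-fold for npas4a, a neuronal factor induced by electrical activity, 2.81-fold for egr4, 2.69-fold for elovl7b, a fatty acid elongase gene, and 2.1-fold for egr1. Log2 fold changes in the authors' deposited table were -1.58 with a standard error of 0.092 for fosab (adjusted p = 2.67e-61), -1.47 with a standard error of 0.090 for npas4a (adjusted p = 1.59e-56), -0.94 for egr1 (adjusted p = 1.89e-35) and -0.98 for the antiproliferative gene btg2 (adjusted p = 2.99e-30).

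Of 12 measured targets of the aryl hydrocarbon receptor, the ligand-activated factor that binds dioxins, 5 rose with TCPM, 7 adjusted over the list alone, and none fell. Their median log2 fold change was 0.25 (cameraPR adjusted p = 1.48e-25). The monooxygenase genes cyp1a (Entrez gene 140634) and cyp1b1 were 2.23-fold and 1.74-fold higher before shrinkage, and the forkhead gene foxq1a 1.61-fold. Their log2 fold changes in the authors' deposited table were 0.97 with a standard error of 0.079 (adjusted p = 1.88e-31), 0.64 with a standard error of 0.086 (adjusted p = 3.71e-11) and 0.54 with a standard error of 0.088 (adjusted p = 3.16e-07). The remaining pair, named after their values were seen, were cyp1c1 at 0.40 (adjusted p = 4.78e-07) and the receptor's repressor ahrra at 0.49 (adjusted p = 0.000429) in the authors' deposited table. Of 58 other genes of xenobiotic metabolism 4 rose, and adjusted over the list alone 6 rose and 1 fell (median 0.07, cameraPR adjusted p = 1.02e-06). They were the efflux transporter gene abcg2a at 0.74 with a standard error of 0.079 (adjusted p = 1.57e-17), the monooxygenase gene cyp3a65 at 0.36 with a standard error of 0.075 (adjusted p = 0.0002), gsta.1 at 0.32 (adjusted p = 0.00261) and ugt5a4 at 0.37 (adjusted p = 0.033) in the authors' deposited table.

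The exocrine pancreas list held 34 measured digestive enzyme genes, of which 4 rose over all genes tested, 15 adjusted over the list alone, and none fell. The list's median log2 fold change was 0.22 (cameraPR adjusted p = 2.3e-18, and 1.94e-09 with a preset correlation of 0.05). Members that move together more than these presets allow would make both p-values too small, which could not be estimated. The serine protease gene prss60.2 at 0.41 with a standard error of 0.085 (adjusted p = 0.000197), the pancreatic phospholipase pla2g1b at 0.34 (adjusted p = 0.00381), cuzd1.1 at 0.40 (adjusted p = 0.0156) and the amylase zgc:92137 at 0.34 (adjusted p = 0.0126) passed in the authors' deposited table. The trypsin gene prss1 at 0.23 with a standard error of 0.105 (adjusted p = 0.438), carboxypeptidase cpa5 at 0.27 (adjusted p = 0.12) and elastase ela2l at 0.07 (adjusted p = 0.956) did not pass there. None of 23 endocrine genes passed in DESeq2, and 0 reached an unadjusted p under 0.05. Their median log2 fold change was 0.04 (cameraPR adjusted p = 0.320). The authors' deposited table gives 0.04 for insulin, ins, with a standard error of 0.097 (adjusted p = 0.977), and 0.18 for glucagon, gcga (adjusted p = 0.594). None of 15 pancreas transcription factor genes passed in DESeq2 either, with 2 lower at an unadjusted p under 0.05, a median of -0.07 and a cameraPR adjusted p of 0.151. Among the matched random lists that median lay low (adjusted p = 0.0381). The progenitor factor pdx1 at 0.18 (adjusted p = 0.712) and the acinar factor ptf1a at -0.07 (adjusted p = 0.958) did not pass in the authors' deposited table.

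Of 34 intestine genes 8 rose with TCPM, 17 adjusted over the list alone, with a median of 0.17 (cameraPR adjusted p = 3.41e-17). They included the fatty acid carrier fabp2 at 0.40 (adjusted p = 2.01e-07), the retinol carrier rbp2a at 0.41 (adjusted p = 1.33e-07) and the chitinase chia.2 at 0.34 (adjusted p = 1.32e-05) in the authors' deposited table. Of 12 mitochondrially encoded transcripts 10 rose, 12 adjusted over the list alone, with a median of 0.27 (cameraPR adjusted p = 1.42e-35). Among them in the authors' deposited table were mt-nd2 at 0.36 with a standard error of 0.058 (adjusted p = 1.32e-07), mt-nd4 at 0.27 (adjusted p = 4.51e-05) and mt-cyb at 0.29 (adjusted p = 7.1e-05). How far these transcripts move together from pool to pool could not be estimated, so the p-value of the list may be too small. The cholesterol list had 2 higher members of 29, msmo1 at 0.39 (adjusted p = 0.00668) and the receptor ldlra at 0.25 (adjusted p = 0.0299) in the authors' deposited table, 2 adjusted over the list alone, with a median of 0.06 and a cameraPR adjusted p of 0.00161.

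Small shifts of whole tissue lists accompanied these changes. The correlation between their members could not be estimated, so the cameraPR p-values may be too small. No lens gene of 65 passed in DESeq2 (0 adjusted over the list alone, 16 higher at an unadjusted p under 0.05), and the lens median was 0.11 (cameraPR adjusted p = 2.39e-11). No neuron or glia gene of 44 passed (2 at an unadjusted p under 0.05), with a median of 0.07 (cameraPR adjusted p = 0.000222). The cell cycle list was lower, with a median of -0.09 and 1 of 43 members past the threshold, the cyclin gene ccnd1, 2 adjusted over the list alone (cameraPR adjusted p = 1.74e-05). The collagen and connective tissue list was also lower, with a median of -0.07 and 1 of 36 members past, the collagen chaperone gene serpinh1b, 3 adjusted over the list alone (cameraPR adjusted p = 1.91e-06). In the heat shock list 5 of 30 genes fell and none rose, 6 fell and 1 rose adjusted over the list alone, and the test placed the list lower (cameraPR adjusted p = 0.00217) although its median was 0.01. The chaperone genes dnajb1b at -0.55 (adjusted p = 7.79e-12) and hsp70l at -0.45 (adjusted p = 0.000186) fell in the authors' deposited table. In the p53 list 3 of 21 fell and 1 rose, 4 and 2 adjusted over the list alone, with a median of -0.01 and a cameraPR adjusted p of 0.00267. Those past the threshold over all genes were btg2, cdkn1a and gadd45ba, which also respond to growth signals, and sesn1 in the other direction. Ranks gave the heat shock and p53 lists adjusted p values of 0.663 and 0.431. Of 51 inflammation genes 4 fell, and 4 adjusted over the list alone, led by the cytokine signal inhibitor socs3a at -0.88 with a standard error of 0.095 (adjusted p = 2.71e-17) in the authors' deposited table. That list had a cameraPR adjusted p of 0.0301, and an adjusted p of 0.214 with a correlation of 0.05. The lists of antioxidant response, fatty acid synthesis, heart and red blood cell genes passed at 0.00818, 0.0308, 0.00818 and 0.0225 but had adjusted p values of 0.0716, 0.12, 0.0582 and 0.132 with that correlation.

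Larvae given TCPMOH were compared with the same DMSO larvae to learn which genes respond to the methanol. They too had more per2 and cry5 and less fosab and npas4a. Heat shock transcripts were higher, and transcripts of the replication genes mcm2 and mcm3 and of the day-phase clock genes nr1d1 and nr1d2a were lower. In the authors' deposited table DESeq2 called 547 of 21491 genes, of which 332 were higher and 215 lower, beside 2080 at an unadjusted p under 0.05. The called genes had a median absolute log2 fold change of 0.50 before shrinkage, and 56 changed by at least 2-fold.

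Before shrinkage cry5 was 3.81-fold, per2 3.64-fold, rdh5 3.21-fold, xpc 2.96-fold and lonrf1 2.79-fold higher with TCPMOH. The authors' deposited table gives log2 fold changes of 1.71 with a standard error of 0.078 for cry5 (adjusted p = 5e-102), 1.59 with a standard error of 0.088 for per2 (adjusted p = 8.27e-70) and 1.4 with a standard error of 0.077 for xpc (adjusted p = 8.63e-70). The uncharacterised genes si:dkey-104n9.1 at 1.31 and si:ch211-161h7.5 at 1.3 also rose in the authors' deposited table. Before shrinkage npas4a was 6.23-fold, fosab 6.21-fold, egr4 3.48-fold, btg2 2.92-fold and nr4a1, an immediate early nuclear receptor gene, 2.34-fold lower. The authors' deposited table has npas4a at -1.83 with a standard error of 0.115 (adjusted p = 1.49e-53), fosab at -1.78 with a standard error of 0.116 (adjusted p = 2.62e-49) and nr4a1 at -1.12 with a standard error of 0.069 (adjusted p = 3.69e-55). Of 39 clock genes 8 rose and 8 fell, 9 and 10 adjusted over the list alone. The cameraPR test placed the clock list higher (adjusted p = 2.61e-05) while its median was -0.03, and by ranks the adjusted p was 0.629. Among the clock genes that fell, named after their values were seen, were the repressors nr1d1 at -0.38 (adjusted p = 1.5e-06) and nr1d2a at -0.68 (adjusted p = 5.93e-19) and per1a at -0.57 (adjusted p = 2.2e-10) in the authors' deposited table.

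In the heat shock list 9 of 30 genes rose with TCPMOH and none fell, 11 rose and 1 fell adjusted over the list alone, and the median was 0.15 (cameraPR adjusted p = 1.92e-16). The authors' deposited table gives 0.54 with a standard error of 0.048 for serpinh1b (Entrez gene 30449, adjusted p = 1.45e-25), 0.41 with a standard error of 0.075 for the chaperone gene hsp90aa1.2 (adjusted p = 5.21e-06) and 0.35 for hsp90aa1.1 (adjusted p = 9.03e-06). Of 43 cell cycle genes 8 fell, 9 adjusted over the list alone, with a median of -0.02 (cameraPR adjusted p = 0.00015). Among them in the authors' deposited table were the replication origin genes mcm2 at -0.48 (adjusted p = 1.17e-05), mcm3 at -0.42 (adjusted p = 0.000236) and orc1 at -0.49 (adjusted p = 0.000112). Of 21 p53 response genes 3 fell, with 3 lower and 1 higher adjusted over the list alone and a median of -0.03 (cameraPR adjusted p = 0.0026). They were btg2, the kinase inhibitor gene cdkn1a at -0.57 (adjusted p = 1.21e-07) and gadd45ba at -0.48 (adjusted p = 0.000436) in the authors' deposited table. Ranks gave the cell cycle and p53 lists adjusted p values of 0.148 and 0.825.

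Of 58 genes of xenobiotic metabolism outside the receptor list, 8 rose with TCPMOH, 12 rose and 2 fell adjusted over the list alone (median 0.07, cameraPR adjusted p = 2.19e-07). The transporter gene abcg2a at 1.03 with a standard error of 0.092 (adjusted p = 3.37e-26), ugt5a4 at 0.62 (adjusted p = 6.53e-05), cyp2y3 at 0.36 (adjusted p = 8.62e-05) and cyp3a65 at 0.39 with a standard error of 0.10 (adjusted p = 0.00565) were higher in the authors' deposited table. None of the 12 aryl hydrocarbon receptor targets passed in DESeq2 (3 higher and 1 lower at an unadjusted p under 0.05, 1 and 1 adjusted over the list alone), with a median of 0.09 and a cameraPR adjusted p of 0.158. Ranked among the matched random lists, however, that median lay high, at percentile 99.84 (adjusted p = 0.0112). The authors' deposited table gives 0.24 with a standard error of 0.096 for cyp1a (adjusted p = 0.252). Cholesterol genes were higher, 3 of 29 over all genes and 6 adjusted over the list alone (median 0.10, cameraPR adjusted p = 2.47e-06), among them msmo1 at 0.64 (adjusted p = 7.96e-09) and dhcr7 at 0.33 (adjusted p = 0.00168) in the authors' deposited table. Of 27 antioxidant genes 2 rose, keap1a, whose product holds the antioxidant regulator Nrf2 inactive, at 0.47 (adjusted p = 6.27e-05) and prdx1 at 0.28 (adjusted p = 0.0354) in the authors' deposited table, 3 adjusted over the list alone, with a median of 0.07 and a cameraPR adjusted p of 0.00206.

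Intestine genes were higher with TCPMOH too, 4 of 34 over all genes and 9 adjusted over the list alone (median 0.13, cameraPR adjusted p = 1.82e-09), including the glucose transporter gene slc5a1 at 0.46 (adjusted p = 1.21e-05) in the authors' deposited table. In the exocrine pancreas list 1 of 34 genes rose, prss60.2 at 0.46 with a standard error of 0.101 (adjusted p = 0.000463) in the authors' deposited table, 1 adjusted over the list alone. The median was 0.07, with a cameraPR adjusted p of 0.00341 and an adjusted p of 0.0622 with a correlation of 0.05. The authors' deposited table gives 0.06 for prss1 with a standard error of 0.111 (adjusted p = 0.977), 0.11 for cpa5 (adjusted p = 0.911) and 0.06 for ela2l (adjusted p = 0.979). None of 23 endocrine genes passed in DESeq2 (3 higher at an unadjusted p under 0.05, cameraPR adjusted p = 0.116). Their median of 0.06 did lie high among the matched random lists (adjusted p = 0.0325). The authors' deposited table has ins at 0.06 (adjusted p = 0.978), gcga at 0.08 (adjusted p = 0.961), pdx1 at 0.25 (adjusted p = 0.49) and ptf1a at -0.01 (adjusted p = 0.996), while gata4, the 1 of 15 pancreas transcription factor genes past the threshold, fell, at -0.42 (adjusted p = 0.0292). That list gave a cameraPR adjusted p of 0.591. No mitochondrially encoded transcript passed in DESeq2 (1 at an unadjusted p under 0.05), and the median of the 12 was 0.13 (cameraPR adjusted p = 0.00476). The photoreceptor list, which also holds visual cycle genes of the retinal pigment epithelium, moved both ways. Of its 52 genes 5 were higher and 7 lower, 6 and 9 adjusted over the list alone, so that the list did not pass (cameraPR adjusted p = 0.327). With TCPM 5 were higher and 1 lower. The phosphodiesterase subunit gene pde6ga at -0.92 (adjusted p = 3.09e-11) fell and the visual cycle genes rpe65a at 0.71 (adjusted p = 1.57e-06) and rlbp1b at 0.60 (adjusted p = 1.79e-05) rose in the authors' deposited table. Lens, fatty acid oxidation, insulin signalling and neuron lists had cameraPR adjusted p values of 0.000941, 0.0136, 0.0194 and 0.0429, and adjusted p values of 0.0622, 0.114, 0.114 and 0.252 with a correlation of 0.05.

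**Figure D1:**
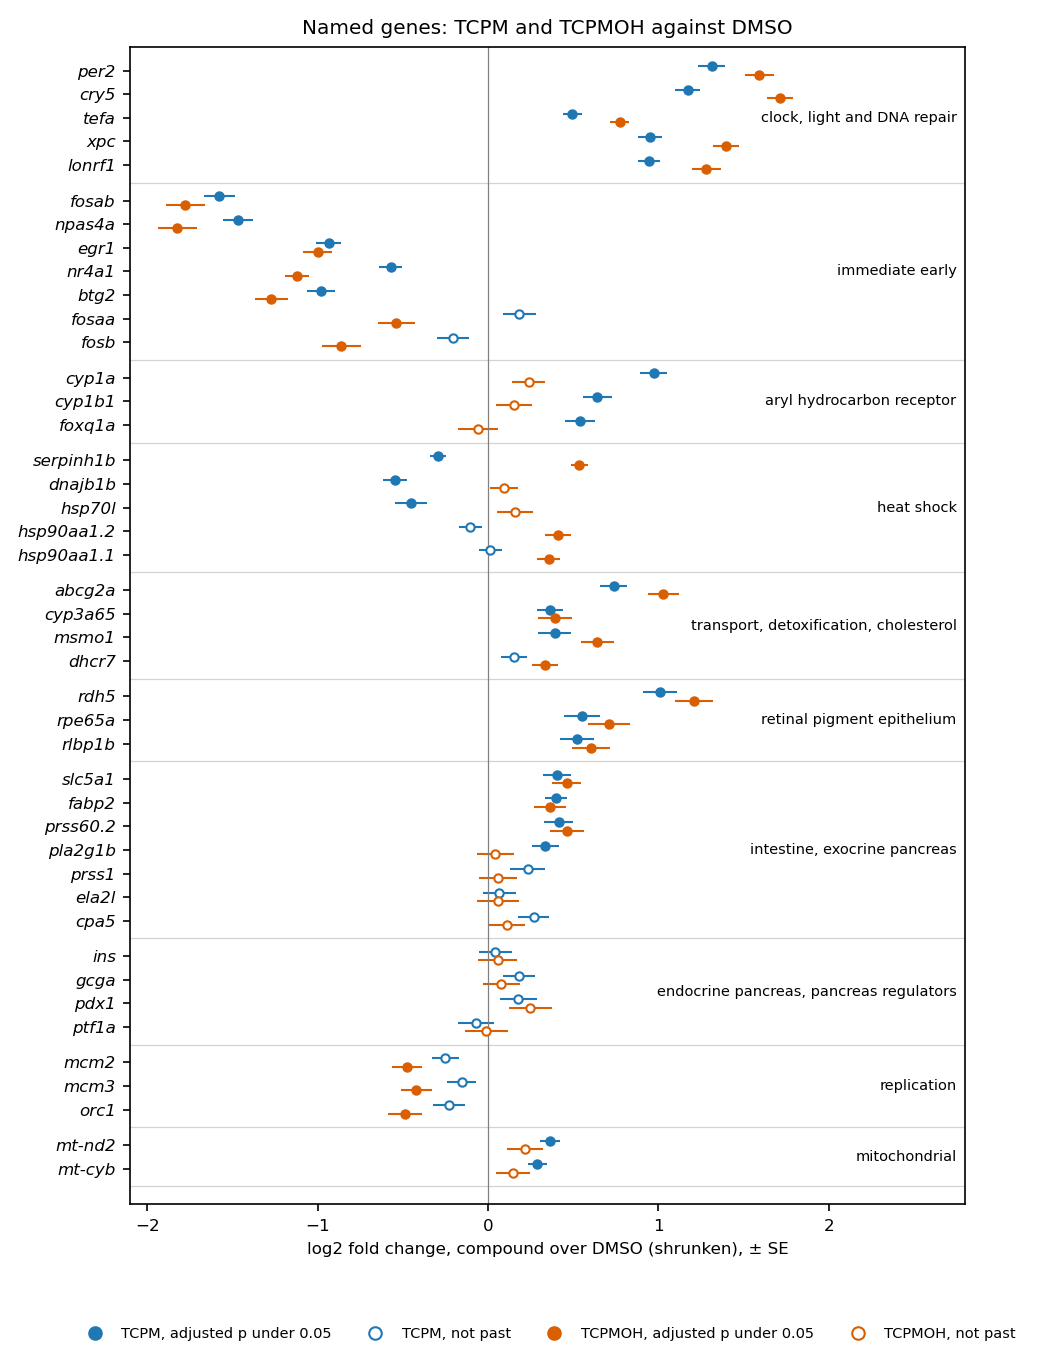
Log2 fold change against DMSO, with the deposited standard error as bars, of named genes with 50 nM TCPM and 50 nM TCPMOH. Filled points have an adjusted p under 0.05; cyp1a lies at 0.97 with TCPM and 0.24 with TCPMOH, and serpinh1b at -0.29 and 0.54.

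The direct comparison of the analogs asked where a hydroxyl in place of a hydrogen went with another response at the same dose and over the same hours. TCPMOH gave less cyp1a, cyp1b1 and foxq1a, more heat shock transcripts, and further movement of many genes that both compounds moved, such as cry5, xpc and nr4a1. The difference of the log2 fold changes passed the threshold for 103 of 22732 genes, 55 higher and 48 lower with TCPMOH. Of these 103 genes, 16 had been called against DMSO with TCPM alone, 36 with TCPMOH alone, 35 with both and 16 with neither. With no covariance from the shared DMSO libraries in the standard error, 15 genes passed.

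The chaperone gene serpinh1b differed most clearly, by 0.83 with a 95% interval of 0.74 to 0.92 (adjusted p = 1.54e-65). It was the only gene called in opposite directions, at -0.29 with a standard error of 0.045 with TCPM and 0.54 with a standard error of 0.048 with TCPMOH in the authors' deposited tables. The heat shock list as a whole lay higher with TCPMOH, by a median of 0.18, with 11 of 30 members past the threshold, 15 higher and 1 lower adjusted over the list alone (cameraPR adjusted p = 2e-46). Among them dnajb1b differed by 0.64 (interval 0.49 to 0.79, adjusted p = 6e-13), hsp70l by 0.61 (interval 0.41 to 0.80, adjusted p = 1.96e-06), hsp90aa1.2 by 0.52 (interval 0.38 to 0.66, adjusted p = 1.33e-09) and hsp90aa1.1 by 0.34 (interval 0.21 to 0.47, adjusted p = 0.000149). The collagen list differed by a median of 0.03 (cameraPR adjusted p = 0.000138), its 1 member past the threshold was serpinh1b, which both lists hold, and by ranks the adjusted p was 0.148.

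Aryl hydrocarbon receptor targets lay lower with TCPMOH than with TCPM by a median of -0.21 over 11 genes (cameraPR adjusted p = 7.76e-18), 4 of them past the threshold and 5 adjusted over the list alone. The differences were -0.73 for cyp1a (interval -0.91 to -0.56, adjusted p = 8.39e-13), -0.60 for foxq1a (interval -0.80 to -0.39, adjusted p = 1.4e-05) and -0.49 for cyp1b1 (interval -0.68 to -0.30, adjusted p = 0.0003). The drug-metabolising monooxygenase gene cyp3a65 did not differ past the threshold, at 0.03 with an interval of -0.15 to 0.21. The transporter gene abcg2a had a difference of 0.29 with an interval of 0.12 to 0.46 and an adjusted p of 0.131.

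Digestive enzyme genes lay lower with TCPMOH than with TCPM by a median of -0.15 over 33 genes (cameraPR adjusted p = 5.09e-07), although 0 of them passed by the normal test of the difference, 0 adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. Single genes had wide intervals, with pla2g1b at -0.29 (interval -0.48 to -0.10, adjusted p = 0.307), prss1 at -0.17 (interval -0.39 to 0.04), cpa5 at -0.16 (interval -0.35 to 0.03), ela2l at -0.01 (interval -0.23 to 0.22) and prss60.2 at 0.05 (interval -0.14 to 0.23). The islet and progenitor genes were not shown to differ or to be equal. On the shrunken scale the intervals were -0.19 to 0.22 for ins, -0.30 to 0.10 for gcga, -0.16 to 0.30 for pdx1 and -0.17 to 0.29 for ptf1a. Before shrinkage they were wider, at -0.27 to 0.31 for ins, -0.40 to 0.13 for gcga, -0.31 to 0.59 for pdx1 and -0.33 to 0.58 for ptf1a. The interval of prss1 was then -0.61 to 0.02. The mitochondrially encoded transcripts lay lower by a median of -0.17 (cameraPR adjusted p = 2.61e-08) and the 83 ribosomal protein genes by -0.06 (adjusted p = 1.73e-05). In those lists 0 genes passed by the same normal test, 1 and 0 adjusted over the list alone, with 5 and 3 lower at an unadjusted p under 0.05. Correlation between members could not be estimated, in these lists or the digestive enzyme list, so the cameraPR p-values may be too small. The thyroid axis list differed by a median of -0.08 over 18 genes (cameraPR adjusted p = 2.76e-05), of which 2 were lower past the threshold and 3 adjusted over the list alone. Those 2 were the thyroglobulin gene tg, which did not pass before shrinkage, and the hormone-responsive factor klf9, which differed by -0.48 (interval -0.67 to -0.30, adjusted p = 0.000273). The stress steroid list holds klf9 too. Of its 25 genes 2 fell with TCPM and 3 with TCPMOH, and none rose (cameraPR adjusted p = 0.0926 and 0.0562). Its member fkbp5 was at -0.40 with TCPM and -0.64 with TCPMOH, a difference of -0.24 (adjusted p = 0.432). Intestine genes did not differ past the threshold as a list, with a median difference of -0.01.

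Other differences in the lower direction were nr4a1 at -0.55 (interval -0.68 to -0.41, adjusted p = 5.36e-12), fosaa at -0.72 (interval -0.93 to -0.52, adjusted p = 7.58e-09) and fosb at -0.66 (interval -0.86 to -0.45, adjusted p = 1.41e-06). In the authors' deposited tables fosaa was at 0.18 with TCPM (adjusted p = 0.602) and -0.54 with TCPMOH (adjusted p = 0.000101), and fosb at -0.21 (adjusted p = 0.458) and -0.86 (adjusted p = 1.96e-11). In the higher direction cry5 differed by 0.54 (interval 0.39 to 0.69, adjusted p = 1.94e-09), xpc by 0.45 (interval 0.30 to 0.59, adjusted p = 1.58e-06) and si:ch1073-440b2.1 by 0.49 (interval 0.36 to 0.62, adjusted p = 6.41e-10). The difference for per2 was 0.28 (interval 0.12 to 0.44, adjusted p = 0.136) and that for fosab -0.20 (interval -0.41 to 0.01), which was -0.56 (interval -0.86 to -0.26, adjusted p = 0.0589) before shrinkage. For npas4a it was -0.36 (interval -0.56 to -0.15, adjusted p = 0.117), and before shrinkage -0.75 (adjusted p = 0.000243), past the threshold on that scale alone.

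**Figure D2:**
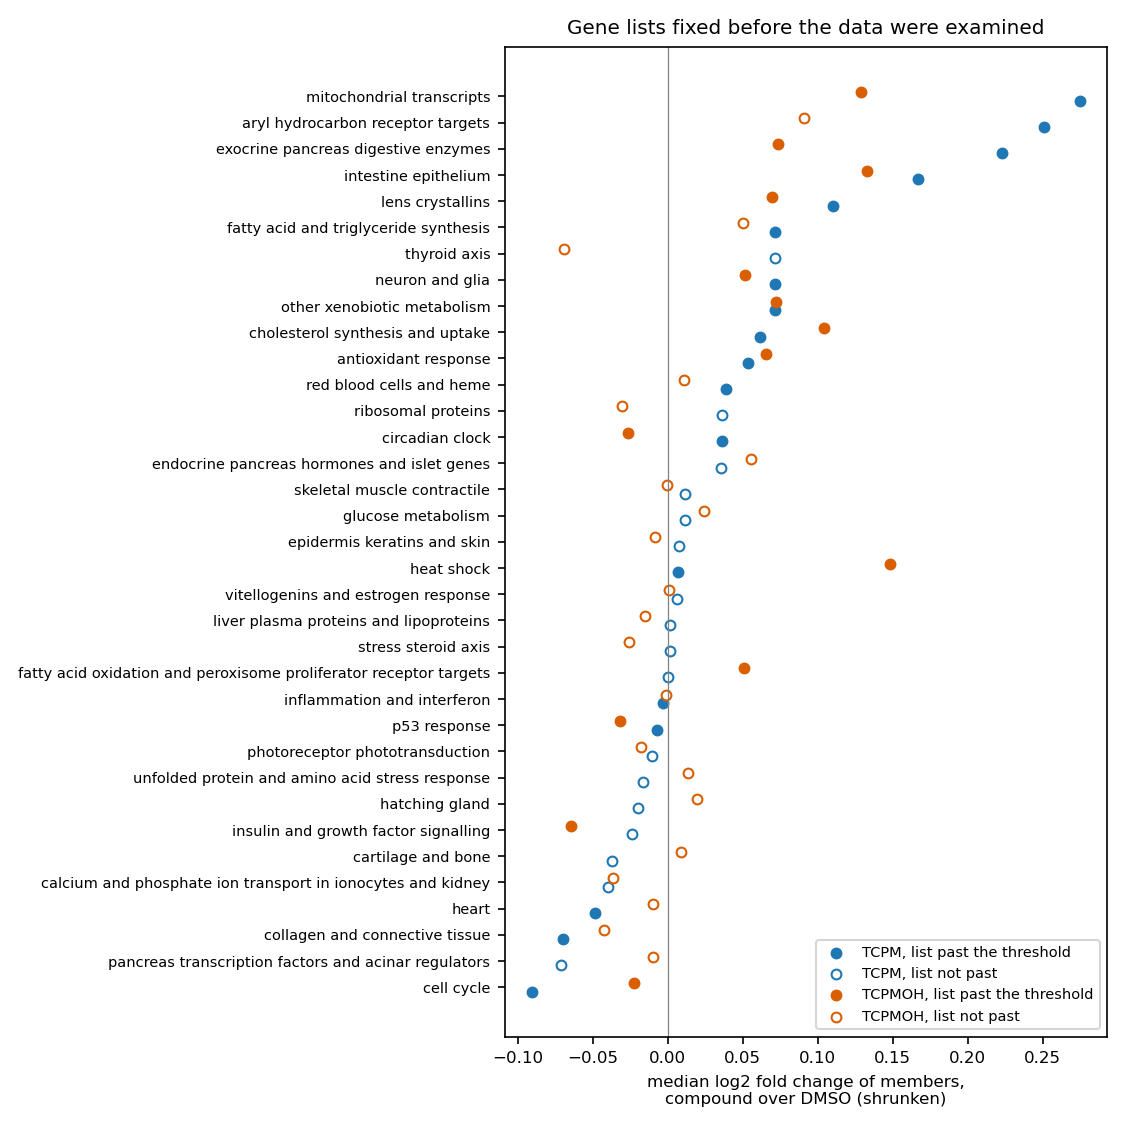
Median log2 fold change of the gene lists with TCPM and TCPMOH against DMSO; filled points are lists with a cameraPR adjusted p under 0.05. The heat shock list lies at 0.01 with TCPM and 0.15 with TCPMOH, the aryl hydrocarbon receptor list at 0.25 and 0.09.

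Many of the same genes changed with both compounds. A total of 162 genes rose and 75 fell with each. Independent lists of the same sizes would share 4.36 and 1.37, and the simulated count for unchanged groups against shared controls was at most 0 over 100 draws, as adjusted p-values leave few calls among unchanged genes. Of all genes only serpinh1b was called in opposite directions among the 238 genes called with both. The genes with the smallest p in both tables were per2, cry5, npas4a, fosab, lonrf1, xpc, btg2 and cyr61, a matrix signalling gene at -0.80 with TCPM and -0.89 with TCPMOH in the authors' deposited tables. Across 22732 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.712 and a Spearman rho of 0.629, beside means of 0.50 and 0.480 simulated with shared controls and no effect. Their covariance was 0.0104 and the simulated one 0.00446, a difference of 0.0059. Part of the excess may come from the DMSO libraries that both fits used, which could not be split.

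Of the 237 genes that changed the same way, 199 moved further with TCPMOH and 38 moved less, by a median of 0.15 before shrinkage. The difference passed the threshold before shrinkage for 33 of them, and all 33 moved further with TCPMOH. They included cry5, xpc, lonrf1, the clock output gene tefa and nr4a1. The 237 genes were chosen by being called with both compounds, so a gene with a larger standard error with TCPMOH needed a larger change there. Part of the split of 199 and 38 may come from that choice, which was not tested.

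**Figure D3:**
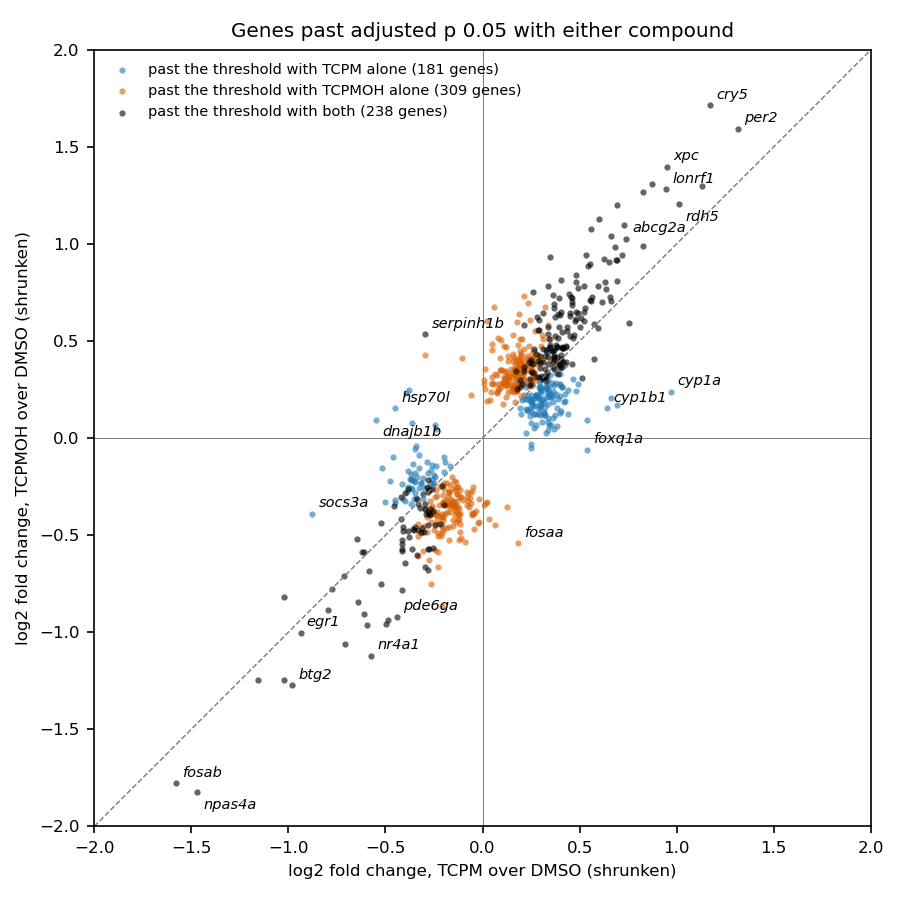
Log2 fold change against DMSO of each gene with TCPM (x axis) and TCPMOH (y axis), as deposited and turned to compound over DMSO. Of the coloured genes 181 were called with TCPM alone, 309 with TCPMOH alone and 238 with both, and serpinh1b lies alone in the quadrant of opposite signs among the last.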

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

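Of the tests in this part, all those that weigh an explanation were chosen only after the result was seen, while the difference between the compounds and the check of size factors were planned. The responses to TCPM and TCPMOH differed past the threshold of the difference test in 103 genes. Lists lower with TCPMOH than with TCPM were those of the aryl hydrocarbon receptor (median -0.21), mitochondrial transcripts (-0.17), exocrine pancreas (-0.15), thyroid axis (-0.077) and ribosomal proteins (-0.061), and higher were heat shock (0.18) and collagen (0.032). Named genes lower with TCPMOH were cyp1a (-0.73), fosaa (-0.72), fosb (-0.66), foxq1a (-0.60), nr4a1 (-0.55), cyp1b1 (-0.49), klf9 (-0.48), pde6ga (-0.48) and ldlra (-0.30). Named genes higher with TCPMOH were serpinh1b (0.83), dnajb1b (0.64), hsp70l (0.61), cry5 (0.54), hsp90aa1.2 (0.52), si:ch1073-440b2.1 (0.49), socs3a (0.49), xpc (0.45), si:dkey-104n9.1 (0.43), hpxa (0.42), hsp90aa1.1 (0.34), lonrf1 (0.33) and tefa (0.28). These differences keep the deposited, shrunken scale, on which each table was shrunken by its own prior. Before shrinkage several were larger, such as fosb at -0.97, pde6ga at -0.94 and hpxa at 0.67, npas4a passed as well (-0.75), and socs3a, ldlra and si:dkey-104n9.1 did not pass.

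Among the size factors of the 4 TCPMOH libraries, 0.929 to 0.998, the highest stood apart, with its gap to the nearest other equal to 0.837 of the group's range. Chance gives such a gap in about 1 of 20 groups, and the 3 groups were checked, DMSO in both fits.

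The genes that changed in the same direction with both compounds were weighed against the shared DMSO libraries and the conditions at collection. For 33 of the 237 the difference between the compounds passed the threshold before shrinkage, where the DMSO libraries cancel, so the controls cannot be their whole account, while for the other 204 a chance deviation of the controls that adds to the calls cannot be excluded without counts per library. A difference in light or time of day of the DMSO larvae alone is argued against as the whole account by the 9 of 39 circadian genes that differed between the compounds past the threshold before shrinkage. A difference in light or time of day at collection that set all 3 groups apart is a candidate explanation. Of the circadian list 41.03% (16 of 39 genes) passed with TCPMOH beside 2.48% of other genes (Fisher's exact test, one-sided, p = 5.49e-16), and 30.8% with TCPM beside 1.83% (p = 4.26e-12). These shares restate the movement of clock genes that raised the explanation, so they cannot favour it over an effect of the compounds. Hours and light at collection are not given in the sources used here, and an effect of both compounds on these genes also stays open and was not tested apart from the collection.

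The heat shock list differed between the compounds, and among its members called against DMSO serpinh1b alone was called with both, in opposite directions. The direct difference was past the threshold in 11 of 30 members both as deposited (cameraPR adjusted p = 2e-46) and before shrinkage. Before shrinkage the DMSO libraries cancel from the difference itself, so a chance deviation of their mean has no part in its size there. That follows from how the difference is built, and these values restate the pattern and are no separate test. The standard error of the difference, and so the calls, still depend on the DMSO libraries and on the assumed covariance. An unequal amount of connective tissue, where serpinh1b is abundant, is argued against by the other 35 collagen genes, whose median difference was 0.0319 (quartiles -0.028 to 0.058) beside a lower bound of 0.74 for serpinh1b. Temperature or handling that differed between the groups cannot be told apart from a compound effect, because the 9 members that moved with TCPMOH all rose and the 5 that moved with TCPM all fell, as either would give. Adjusted over the list alone the movement was not fully one way, with 11 higher and 1 lower with TCPMOH and 1 higher and 6 lower with TCPM.

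The aryl hydrocarbon receptor targets were higher with TCPM and, as a list, lower with TCPMOH than with TCPM. A light response of the targets like that of cry5 and xpc is argued against, because these 2 genes rose further with TCPMOH while the targets lay lower, by a median of -0.211 (cameraPR adjusted p = 7.76e-18). A shift of clock phase stays open for the difference between the compounds, since 5 of 39 circadian genes also lay lower with TCPMOH past the threshold before shrinkage. The clock genes moved both ways, however. As deposited 5 lay lower and 4 higher, and their list did not pass (cameraPR adjusted p = 0.0645). More intestine in the larvae given TCPM is argued against for the difference between the compounds by the intestine list, whose median difference was -0.0126 (quartiles -0.044 to 0.055). As the whole account of the rise against DMSO it is not settled by the larvae given TCPMOH alone. There the intestine list rose by a median of 0.13, while the targets had a median of 0.09 and 0 of 12 passed. That median of the targets still lay high among matched random lists (adjusted p = 0.0112), so they were not shown to be unmoved. Only the direct difference argues against it as the whole account, and only if intestine acts alike with both compounds. A part in the rise cannot be told apart from a response of the targets, because the intestine list rose with TCPM too, by a median of 0.167 (quartiles -0.015 to 0.271) beside 0.25 for the targets. No test here excludes other technical differences between the groups, and an activation of the receptor by TCPM, its impurities or its products stays an untested hypothesis.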

How the results depend on the processing

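Of the alternatives, those with fold changes before shrinkage were chosen only after the data were seen. The counts of called genes stayed within 1.5 times of 419 and 547 under an adjusted p under 0.10, 3 other Benjamini-Hochberg adjustments, an empirical null and centred fold changes, from 333 to 538 for TCPM and from 489 to 711 for TCPMOH. With an adjusted p under 0.01 they were 262 and 363, with an absolute log2 fold change of at least 1 as well 9 and 22, and before shrinkage 26 and 56, as stricter limits give. The genes that differ between the compounds numbered 95 to 121 under 3 alternatives and 15 without the covariance of the shared controls, which widens every standard error. The correlation of 0.712 was 0.749 with a base mean of at least 100, 0.703 with no minimum and 0.720 with Wald scores. The overlap of 237 was 231 and 297. Lists passed in 13 to 20 cases with TCPM, in 9 with TCPMOH at a correlation of 0.05 and in 11 for the difference at a correlation of 0. Of 144 named results against DMSO 0 changed direction, 4 were lost with an adjustment over every gene, 4 with the empirical null, 11 at 0.01, 70 with an absolute log2 fold change of at least 1 as well and 61 with that limit before shrinkage. Before shrinkage the 103 differences had a median size of 0.51 in place of 0.43, and 14 were over 1.5 times as large, among them those of pde6ga (-0.94) and hpxa (0.67). On that scale 11 of the 103 genes did not pass and 6 others did. The difference of ela2l turned from -0.01 to 0.015 before shrinkage, within its interval. For the circadian list with TCPMOH, whose members go both ways, the direction turned by ranks (adjusted p = 0.629) and by its median among matched lists (adjusted p = 0.0642), and the cause was not tested. Leaving out each library, another normalization, other splits of the libraries and split controls were not run, since they need counts per library. No paired analysis was possible because which library came from which of the 3 experimental replicates is not given in the sources used here, and the tables hold no values per library. Genes with a base mean under 13.8 and 18.4 had no adjusted p, so depth limits what could be called among them.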

Other observations

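All tests in this part were chosen only after the data were seen. So were its gene lists, other than the circadian list, and their p-values describe patterns already seen and are no separate evidence for them. Pigment cell and retinal pigment epithelium genes were higher with both compounds. Of 18 genes of melanin synthesis and the melanosome, 12 rose with TCPM (median log2 fold change 0.42, cameraPR adjusted p = 4.75e-53) and 11 with TCPMOH (median 0.44, adjusted p = 3.95e-56), and 14 with each adjusted over the list alone. In the authors' deposited tables dct, an enzyme of melanin synthesis, was at 0.83 and 0.99, tyrp1b at 0.63 and 0.77, the melanosome matrix gene pmela at 0.60 and 0.78 and oca2 at 0.53 and 0.67 with TCPM and TCPMOH. Of 29 genes of the retinal pigment epithelium and visual cycle 15 and 16 rose (medians 0.29 and 0.40, adjusted p = 4.76e-48 and 2.09e-46). The authors' deposited tables give 0.66 and 0.73 for the retinol receptor gene stra6, 0.63 and 0.80 for the photoisomerase gene rgra and 0.69 and 0.92 for the lactate transporter gene slc16a8. Between the compounds the differences were small, with medians of 0.06 in both lists (adjusted p = 0.0107 and 0.00354), and by the normal test 0 of their genes passed, with 1 and 4 at an unadjusted p under 0.05.

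Immediate early genes were lower as a group. Of 41 of them 16 fell with TCPM (median -0.21, cameraPR adjusted p = 1.16e-93) and 23 with TCPMOH (median -0.36, adjusted p = 7.49e-124), 22 and 31 adjusted over the list alone, and none rose with either. Among them junbb was at -0.78 and -0.78, the phosphatase gene dusp1 at -0.71 and -0.71 and ier2b at -0.71 and -1.06 in the authors' deposited tables. The list lay lower with TCPMOH than with TCPM by a median of -0.12, with 5 members past the threshold (adjusted p = 1.93e-19).

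Light-responsive repair and photolyase genes and clock genes moved with both compounds. Of 19 repair genes 8 rose with TCPM and 9 with TCPMOH (medians 0.09 and 0.21, adjusted p = 2.43e-54 and 1.14e-99), including ddb2 at 0.69 and 0.92, ercc6 at 0.52 and 0.78 and cry-dash at 0.62 and 0.92 in the authors' deposited tables. Of 14 clock genes of the early day 3 fell with TCPM and 8 with TCPMOH (medians -0.06 and -0.30, adjusted p = 0.000254 and 1.03e-28), such as dbpb at -0.28 and -0.57 in the authors' deposited tables. Of 11 clock genes of the night 2 rose with each (medians 0.05 and 0.01, adjusted p = 0.00298 and 0.000553, but 0.102 and 0.374 by ranks), among them npas2 at 0.73 and 1.1 in the authors' deposited tables. Both the repair and the early day list differed between the compounds, by medians of 0.20 and -0.20 (adjusted p = 2.26e-24 and 5.82e-23), and the night list did not pass there (adjusted p = 0.244). A shift in light or hour of the DMSO larvae alone is argued against as the whole account by the 9 of 39 genes of the circadian list, fixed before the data were seen, that differed between the compounds past the threshold before shrinkage, where the DMSO libraries cancel. Light or hour of collection that set all 3 groups apart may have a part in the movement, and a direct effect of the compounds stays open and untested. The 41.03% of the circadian list that passed with TCPMOH raised the first hypothesis and cannot tell the 2 apart.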
